A study of Mus musculus with 12 samples.

How the data were processed

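Bilateral hippocampus of male C57BL/6 mice aged 12 to 14 months was profiled on one-colour arrays that carry probes for mRNAs and long noncoding RNAs (lncRNAs). There were 6 mice that had undergone tibia fracture surgery, labelled POCD in the series, and 6 that had received no treatment or surgery, with 1 array per mouse. Groups were taken from the sample labels. The labels' numbers 1 to 6 occur in both groups, but they were not treated as pairs.

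Per the labels' protocols, total RNA was extracted with TRIzol, amplified linearly and labelled with Cy3. Spot intensity was extracted with Agilent Feature Extraction, version 11.5.1.1 per the file headers and version 10.7 per the submitters' processing notes. The deposited scanner tables hold intensity on a linear scale, background-subtracted per spot per the file headers and not normalized between arrays, and flags for each spot. The series matrix deposited by the authors holds log2 values. Set against the scanner tables, it was the mean log2 processed signal over a probe's spots minus the array's 75th percentile, within 0.001 for 96.4 to 99.8% of probes. Its column medians ranged from -2.24 to -2.07.

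The main values were log2 processed signal minus each array's 75th percentile, taken over all noncontrol probes. Control spots were left out, and so were spots flagged as nonuniform or population outliers. Spots of one probe were averaged. A probe entered the fit when it was well above background on at least 6 of the 12 arrays, whatever their group, and kept at least 3 values per group. Of 97836 probes, 77508 passed the background filter, and 652 of these had too few values, which left 76856. The handling of flagged spots, the spots behind the percentile and the minimum of 3 values were not fixed before the data were examined. Counts were seen first with flagged spots kept (30 changed probes) and then with the percentile taken after leaving them out (19), before the version used here (21) was adopted. The last leaves out flagged spots from the values and still scales on all of an array's probes. All 3 counts are given with the alternatives.

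POCD was compared with control in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, a two-sided moderated test with Benjamini-Hochberg adjustment at 0.05 and no covariate. The design and the gene lists were fixed before the data were examined. Gene-level values used the probe with the highest mean over all 12 arrays. Gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. Single values per array were compared by an exact two-sided permutation test over all 924 splits, whose smallest p is 0.0022. The arrays lay on 3 slides, each with 2 control and 2 POCD arrays and its own scan date. Slide was therefore tested as a block, and values within each slide are given. Control arrays always took positions 1 and 2 and POCD arrays positions 3 and 4, so that position and group cannot be told apart.

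No column of the files pairs probes with gene symbols. Of 13019 probes carrying RefSeq accessions, 4658 were named through the given RefSeq gene table (assembly GRCm38.p6), and of 15675 RIKEN clone probes 1541 were named through clone symbols or synonyms. A further 27 probes carried names of their own. In all 6226 probes were named. The grid file names build mm9, so the table served for names and neighbouring genes only, and no coordinates are given. The neighbouring genes of Gm39515 are not reported here. The 39027 Agilent catalogue probes could not be named here. They are called mRNA probes because the series profiles mRNAs and lncRNAs and most other probes carry noncoding identifiers. All other probes are called noncoding or lncRNA probes, but no column states the class. Some catalogue probes may detect noncoding transcripts. Some RIKEN clone probes may detect protein-coding ones, since a clone name does not state the class. Without names for the catalogue probes, 1 of 60 fixed gene lists, known lncRNAs, had 5 or more named members. The other lists, among them inflammation, stress, synapse and cell type markers, had at most 1 named member each and were not tested.

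Named genes followed a rule fixed before the data were examined. It took the largest changes past the threshold that were at or above the median signal with no overlap between groups, up to 10 in each direction not counting predicted symbols and up to 3 noncoding genes of any symbol in each direction. Up to 4 members of each changed list and up to 2 of each inflammation, stress, synapse or cell type list were to be added, and where fewer than 20 genes passed, those with the smallest p made up 20. That gave 20 genes. The 4 members of the known lncRNA list with the smallest p were added after the data were examined. For a gene not well above background on any array of a group, a floored fold between group means was computed. The dim group entered with the higher, per array, of its own signal and the lowest signal well above background. Where its own signal was the higher on every array, the floored fold equals the measured fold and is no bound.

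Alternatives were quantile normalization, normexp background correction with an offset of 50 and quantile normalization, array medians for centring, no filter on dim probes, a filter requiring all 12 arrays, the series matrix values, blocks for replicate number and slide, array weights, eBayes with trend and robust settings, and each array left out. The normexp alternative used the median spot signal because the tables hold no mean signal column. The planned ordinary t-test, the mean of all probes of a gene and the other set tests were also run. Alternatives chosen after the data were examined are named as such in the closing section. The steps were tested on simulated data with 76856 probes and 200 changed ones. They recovered 40.3% of changes of 0.5, 88.1% of changes of 1 and 100% of changes of 2 on the log2 scale, with 5 calls on unchanged probes. The simulated probes were drawn independently, without differences shared by a slide or an array, so these shares may not hold for the real arrays. The number of arrays limits the precision. The labels number the tissues within each group, and each was taken as 1 mouse, so that p-values measure the spread between these 12 arrays.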

Results

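Expression of lncRNAs and mRNAs was measured in the hippocampus of aged male mice, to ask which transcripts differ between mice after tibia fracture surgery, a model of postoperative cognitive dysfunction (POCD), and untreated mice. Each group held 6 mice. The 75th percentile of signal ranged from 394 to 542 over the 12 arrays, and no spot was saturated. Of the 97836 probes, 80.9% ± 1.4 (SD, n = 6) were well above background on control arrays and 77.0% ± 1.6 (SD, n = 6) on POCD arrays, a difference of -3.85 percentage points (exact two-sided permutation test, p = 0.0022, adjusted p = 0.011 over 5 array measures). Within slides 1, 2 and 3 this difference was -0.96, -5.81 and -4.77 points. Negative control spots also differed, with a mean background-subtracted signal of -4.69 ± 0.53 (SD, n = 6) on control and -6.55 ± 0.66 (SD, n = 6) on POCD arrays (exact permutation p = 0.0043, adjusted p = 0.011).

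**Figure D1:**
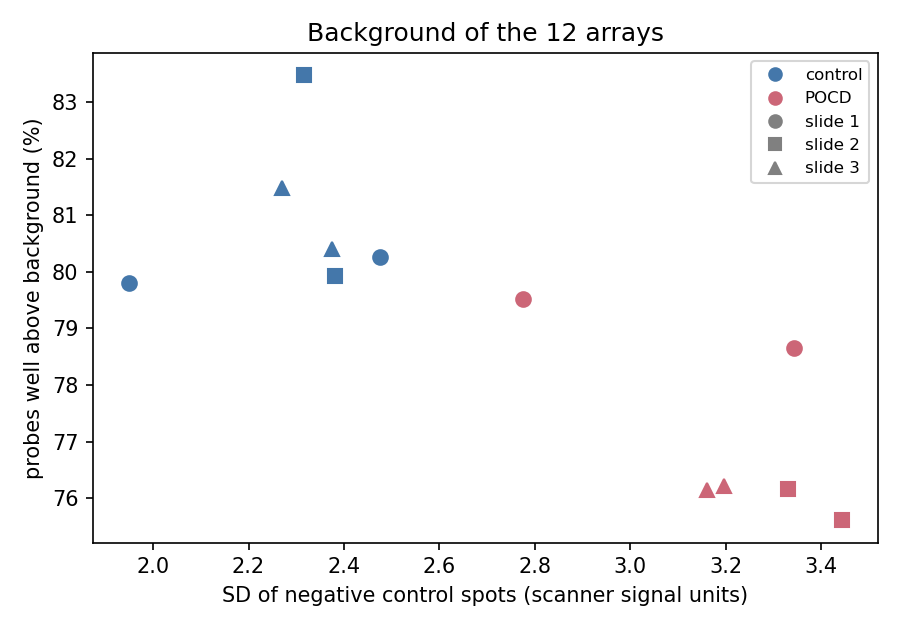
Each point is 1 array, with the SD of its negative control spots in scanner signal units on the x axis and the percentage of probes well above background on the y axis. Colours mark the groups and symbols the 3 slides. All 6 control arrays lie at 79.8% or higher, and all 6 POCD arrays at 79.5% or lower.

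Among named genes, 5 lncRNA genes differed between POCD and control, 3 of them higher and 2 lower in POCD. Adjustment was over the 3914 named genes tested. Surgery and position on the slide cannot be told apart for these genes. Over all 76856 probes 2 of the 5 passed, both lower (4732491K20Rik and 2310015A10Rik), and the 3 higher genes had adjusted p-values of 0.055 for Gm39515, 0.073 for A730020M07Rik and 0.075 for Gm34352. With slide as a block 1 of the 5 passed over all probes, A730020M07Rik (adjusted p = 0.040), and the adjusted p-values were 0.057 for 4732491K20Rik, 0.064 for 2310015A10Rik and 0.080 for Gm39515 and Gm34352. A730020M07Rik rose 1.85-fold, with a log2 fold change of 0.89 ± 0.15 (SE, n = 6 per group, adjusted p = 0.041). It lies beside Slc44a3. Gm39515 rose 1.67-fold (0.74 ± 0.12 SE, adjusted p = 0.035). Gm34352, between the homeobox gene En1 and the sterol regulator gene Insig2, rose 1.66-fold (0.73 ± 0.13 SE, adjusted p = 0.042).

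In the other direction, 4732491K20Rik, between the kinase gene Map3k4 and the plasminogen gene Plg, fell 1.73-fold, with a log2 fold change of -0.79 ± 0.12 (SE, n = 6 per group, adjusted p = 0.032). It was well above background on 6 control arrays and 1 POCD array. The transcript 2310015A10Rik, a neighbour of the alpha-actinin gene Actn1, fell 1.44-fold (-0.52 ± 0.09 SE, adjusted p = 0.035), and a second probe gave -0.14. It was the only one of the 5 at or above the median signal of tested probes. The groups did not overlap for any of the 5 genes, which were chosen on these same values, nor for 1.59% of all tested probes. With slide as a block their adjusted p-values over the named genes were 0.041 to 0.046. The signs were the same within each of the 3 slides, the slides being part of the data on which the 5 were chosen. Without slide 1, a choice made after the data were examined, 0 genes passed in limma. Using the mean of all probes of a gene, 1 gene passed. Quantile normalization gave 3 genes, 1 higher and 2 lower, and so did centring on array medians. Other settings gave more, with 9 genes (6 higher, 3 lower) for quantile normalization with slide as a block, a choice made after the data were examined, 23 (9 higher, 14 lower) for array weights, 44 (26 higher, 18 lower) for normexp with quantile normalization and 498 (448 higher, 50 lower) without a filter on dim probes. With normexp the log2 fold changes of the 5 were smaller, 0.41 for A730020M07Rik, 0.31 for Gm39515 and -0.38 for 2310015A10Rik, which passed, and -0.21 for 4732491K20Rik (adjusted p = 0.067) and 0.25 for Gm34352 (adjusted p = 0.086), which did not. The count was 0 without control replicate 2, 3, 4 or 6 or POCD replicate 3 or 5, and 1 without POCD replicate 2. It was 3 without control replicate 5 or POCD replicate 1, 4 or 6, and 5 without control replicate 1. These counts include genes other than the 5. Of the 5 themselves, 4 passed without control replicate 1 and 3 without control replicate 5. Only 2 passed without POCD replicate 6, and 1 without POCD replicate 1, 2 or 4.

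**Figure D2:**
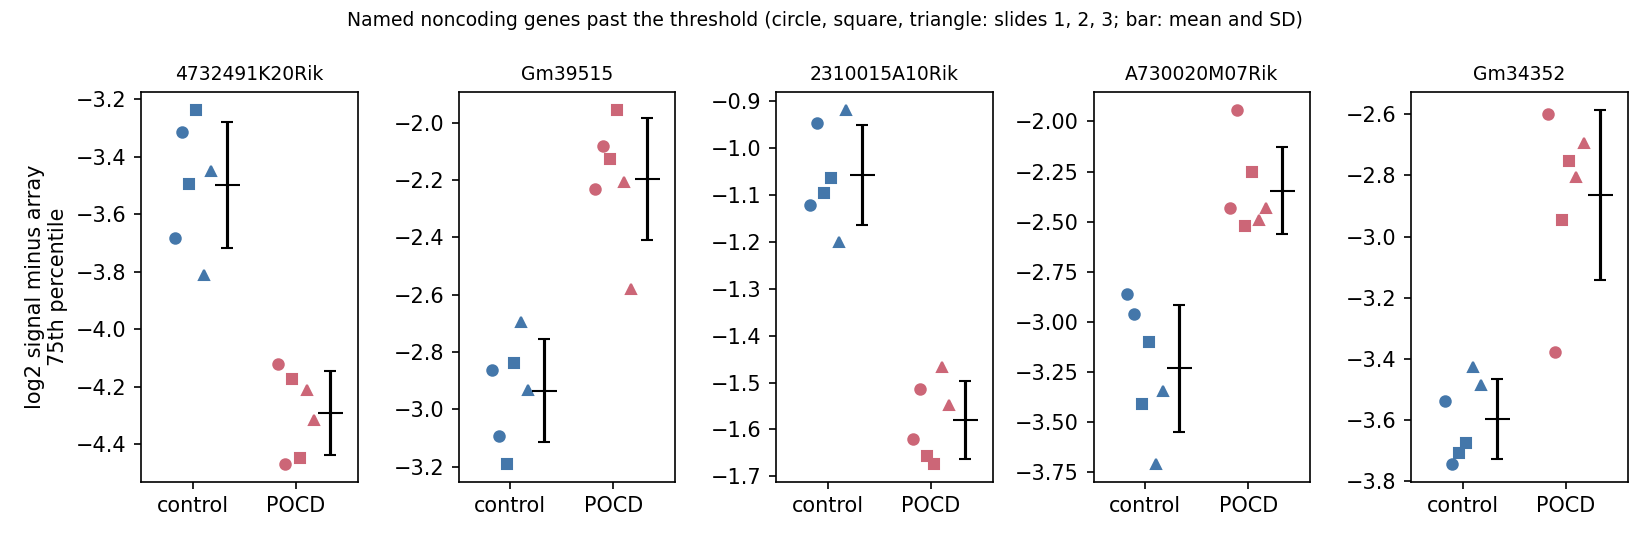
The 5 panels show the 5 named lncRNA genes past the threshold, with log2 signal minus the array's 75th percentile on the y axis and the 2 groups on the x axis. Points are single arrays, symbols mark the 3 slides, and bars give the mean and SD. The highest array of one group lies below the lowest of the other in each panel.

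A further 15 genes with the smallest p-values did not pass the threshold and are given as values. Their adjusted p-values lay between 0.075 and 0.094. With slide as a block 1 of them passed, 1700048M11Rik (adjusted p = 0.046). Without a filter on dim probes all 15 passed, with array weights 12, with normexp 7, with quantile normalization and slide as a block 3, and with eBayes with trend and robust settings 2. The highest log2 fold change was 1.48 ± 0.28 (SE) for 4930527B05Rik, which was well above background on 4 control and 6 POCD arrays, and it was 0.51 with normexp. Gm30088, between the potassium channel gene Kcnk2 and Cenpf, was well above background on 6 control arrays and 0 POCD arrays. Control was 2.23-fold higher, with an adjusted p of 0.094 in limma. The floored fold had the same value and so set no lower limit. The log2 fold change of Gm30088 went from -1.16 to -0.27 with normexp. Gm42318, beside Matn1 and Ptpru, had a log2 fold change of -1.12 ± 0.24 (SE), and Gm32245, between Slc22a12 and Rps6ka4, of -0.83 ± 0.16 (SE). For 9430053O09Rik, between Usp25 and Cxadr, the value was -0.54 ± 0.12 (SE). With normexp 17 of all 24 named genes had log2 fold changes over 1.5 times smaller, so the sizes given here depend on the processing. Higher signal in POCD was measured for Gm30184, between Fat4 and Intu (0.81 ± 0.16 SE), Gm33134, beside Rhob (0.73 ± 0.15 SE), 4921513I03Rik, between Hmga2 and Msrb3 (0.64 ± 0.13 SE), Gm30283, which overlaps Apobec2 (0.62 ± 0.12 SE), and Gm34772, between Dact2 and Smoc2 (0.51 ± 0.11 SE). Lower signal was measured for 1700018L02Rik, which overlaps the adenylate kinase gene Ak3 (-0.65 ± 0.13 SE), Gm36180, which overlaps the complement factor I gene Cfi (-0.63 ± 0.14 SE), Gm38777, beside Gpr37 (-0.56 ± 0.12 SE), 1700048M11Rik, which overlaps Smim11 (-0.55 ± 0.11 SE), and E130317F20Rik, which overlaps the splicing regulator gene Ptbp1 (-0.50 ± 0.11 SE).

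Of the fixed list of known lncRNAs, 20 were on the array and 14 were tested. None passed the threshold over all 3914 genes in limma. An unadjusted p under 0.05 was found for 4 of the 14, against 594 (15.2%) of the 3914, and 1 passed adjusted over the list alone. That gene was Ftx, a transcript of the X-inactivation centre, with a log2 fold change of 0.43 ± 0.12 (SE, n = 6 per group, adjusted p = 0.16 over all genes and 0.044 over the list), and a second probe gave 0.16. Over all genes its adjusted p was 0.049 with normexp and 0.047 without a filter on dim probes. Sox2ot, which overlaps the transcription factor gene Sox2, had a value of -0.45 ± 0.16 (SE), and a second probe gave -0.30. Rmst, a transcript involved in neurogenesis, had a value of 0.38 ± 0.14 (SE), and Snhg8, a host gene of small nucleolar RNAs, of -0.32 ± 0.11 (SE). These 3 had an adjusted p of 0.054 over the list alone. Within slides 1, 2 and 3 the value of Ftx was 0.74, 0.32 and 0.23. It was 0.64, 0.46 and 0.04 for Rmst and -0.65, -0.26 and -0.05 for Snhg8, so that slide 1 gave the largest size for each. For Sox2ot it was -0.37, -0.40 and -0.59, with the largest size on slide 3. The imprinted transcripts Meg3 (-0.06 ± 0.10 SE), Peg13 (-0.04 ± 0.12 SE) and Kcnq1ot1 (0.03 ± 0.11 SE) and Norad (-0.10 ± 0.14 SE) lay within 1 SE of 0.

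By sign, 8 of the 14 were higher and 6 lower in POCD. The list's median and mean were both 0.02, against a median of 0.06 over all genes. The list as a whole did not pass in camera (direction down, adjusted p = 0.59, and adjusted p = 0.58 with an estimated correlation). As 1 list was tested, adjusted and unadjusted p are equal. In limma's fry, which tests the list's own genes, the direction was up (adjusted p = 0.61), and change in either direction had an adjusted p of 0.0074. With slide as a block these were 0.55 in camera and 0.0015 in fry's test for either direction. Fry does not set the list against other genes, and 15.2% of all 3914 named genes had an unadjusted p under 0.05. Its test for either direction therefore cannot show a change particular to this list. Neat1 and Tsix were not well above background on any array, Bc1 and Hotair were on 1 POCD array each, and 2610307P16Rik was on 1 control array. Rian kept too few values after outlier spots were left out.

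**Figure D3:**
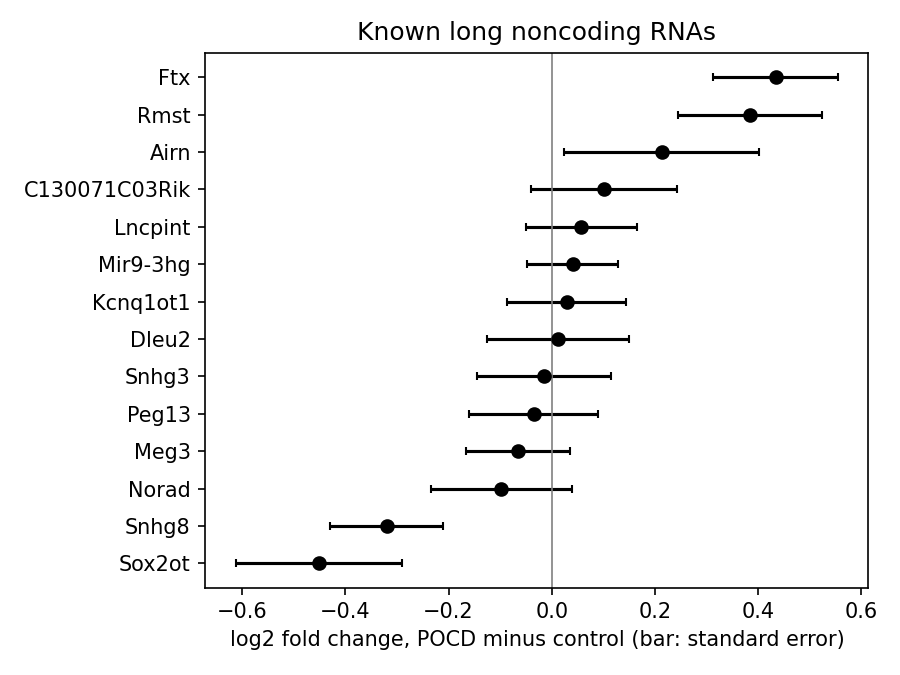
Points give the log2 fold change, POCD minus control, of the 14 known lncRNAs tested, and bars the standard error from limma. The values run from -0.45 for Sox2ot to 0.43 for Ftx, with 8 above 0 and 6 below.

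Over all probes, 21 of 76856 changed, 3 higher and 18 lower in POCD. Of the 33082 mRNA probes tested, 13 changed, 2 higher and 11 lower. Of the 43774 lncRNA probes, 8 changed, 1 higher and 7 lower. RIKEN clone probes, whose class is uncertain, made up 12538 of the 43774, with 1 changed higher and 3 lower. A change of at least 2-fold was found for 5, of which 1 was higher. Among the lower ones, A_51_P204715 (-1.23) and a RefSeq probe (-1.58) were well above background on 6 control and 0 POCD arrays. So was the lower RIKEN clone probe 2310051D24 (-0.95). These entered the fit through control arrays alone. The 3 higher probes were well above background on all 12 arrays. The arrays of the 2 groups were fully separated for each of the 21 probes and for 1.59% of all tested probes, where chance gives 0.22%. At an unadjusted p under 0.05 there were 11506 probes (14.97%), against 3843 expected with no change. Of these, 5490 were higher and 6016 lower. Within slides 1, 2 and 3 the shares at this level were 12.3%, 5.03% and 5.47%, with 0 changed probes in each in limma, and the signs of all 21 were the same in each slide, the slides being part of the data on which the 21 were chosen.

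Because catalogue probes have no gene name here, 2 probes of each direction were singled out after their values were seen. A_51_P346938 rose 3.49-fold (log2 1.80 ± 0.21 SE, adjusted p = 0.040) and A_51_P110341 rose 1.66-fold (0.73 ± 0.10 SE, adjusted p = 0.040). A_52_P624415 fell 2.20-fold (-1.14 ± 0.16 SE, adjusted p = 0.040) and A_52_P27075 fell 2.11-fold (-1.07 ± 0.13 SE, adjusted p = 0.040).

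The probe counts depended on single arrays and on scaling. Leaving out control replicate 1, 2, 4, 5 or 6 or POCD replicate 2, 5 or 6 gave 0 changed probes. Without control replicate 3 there were 3, without POCD replicate 3 there were 4, without POCD replicate 4 there were 7 and without POCD replicate 1 there were 48. Without slide 1 there was 1. Quantile normalization gave 28 changed probes, 10 higher and 18 lower. Of its mRNA probes 7 were higher and 11 lower, of its lncRNA probes 3 and 7, and of those with a 2-fold change 3 and 1. Among those at an unadjusted p under 0.05, quantile normalization moved the share higher in POCD from 47.7% to 65.8%, while centring on the median moved it to 34.0%. With slide as a block 15 probes changed, 4 higher and 11 lower, of which 11 were among the 21. The majority turned in other settings, with 64 higher and 57 lower for normexp with quantile normalization, 4102 higher and 596 lower without a filter on dim probes, and 2 higher and 1 lower for quantile normalization with slide as a block. With the percentile taken without flagged spots 9 were higher and 10 lower.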

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

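The tests of slide, of slide position and of the background on POCD arrays were chosen after the results were seen. In the array values of 3 named genes, control replicate 2 lay far below the other 5 control arrays. Its normalized log2 signal was -4.73 for Gm30184, where the others ran from -4.09 to -3.76. For 4921513I03Rik it was -3.67 against -3.32 to -3.12, and for Gm34772 -3.03 against -2.63 to -2.45. Of 70 groups of 6 values checked, 3 had such an array, and chance gives about 1 in 20, or 3.5. Without that array the changed probes went from 21 to 0. The same drop followed from leaving out control replicate 1, 4, 5 or 6 or POCD replicate 2, 5 or 6, so it is not particular to control replicate 2.

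The real grouping gave more changed probes than other splits of the 12 arrays. Of 100 splits drawn from the 462 possible, 1, the real one, gave as many as 21, and the highest other gave 5. The same held for the 13 mRNA probes (1 split, highest other 2), the 8 lncRNA probes (1 split, highest other 4), the 5 probes with a 2-fold change (1 split, highest other 1) and the 5 named genes (1 split, highest other 1). Chance as a source of these counts is excluded at 0.05, for the version of the values adopted after 3 had been seen. For the 11506 probes at an unadjusted p under 0.05, 4 of the 100 splits, the real one included, gave as many, and the highest gave 17178. The split with 17178 exchanged control replicate 4 with POCD replicate 6 and kept the other arrays in their groups. Because the 100 were drawn from 462 possible splits, they do not settle whether the share over all 462 is under 0.05. Chance is therefore not excluded for this count.

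In limma 14.97% of probes had an unadjusted p under 0.05 between the groups, a count for which chance is not excluded. The share was 16.7% with slide as a block, which decides nothing about slide, since each slide held 2 arrays of both groups, so that the block cannot change the fold of a probe with all 12 values. It was 12.3% within slide 1 and 5.03% and 5.47% within slides 2 and 3, and 6.71% without slide 1, so that a difference particular to slide 1 stays open. Independent noise of single probes is argued against by the fold changes of the 2 brightest probes of 173 genes, which correlated across genes (r = 0.42, rho = 0.44, 95% of 10000 shuffles from -0.15 to 0.15), genes not being independent replicates and shared differences between arrays not being excluded. Position on the slide cannot be told apart from surgery, because 0 positions held both groups, and surgery itself stays open as a possible explanation.

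Fewer probes were well above background on POCD arrays, 77.0% against 80.9%. A general fall of dim transcripts stays open. The dimmest 20% of all probes had a median log2 fold change of 0.29 (exact permutation p = 0.0022, the smallest these splits can give), but 2.14% of them passed the background filter, so this value does not decide about transcript levels. A wider spread of negative control spots is a candidate explanation, as it enters the rule for being above background. Their SD was 3.21 ± 0.24 (SD, n = 6) on POCD and 2.29 ± 0.18 (SD, n = 6) on control arrays, a difference of 0.91 (exact permutation p = 0.0022), and 0.85, 1.04 and 0.86 within the 3 slides. Lower signal of POCD arrays stays open, with a difference in the 75th percentile of 27.5 towards POCD (exact permutation p = 0.33), as do position and surgery.

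Noncoding probes had a median log2 fold change of 0.05 and catalogue probes of -0.06. The difference between the classes, measured per array, was 0.11 higher in POCD (exact permutation p = 0.16), and 0.28, 0.06 and -0.02 within slides 1, 2 and 3. In 20 bins of equal signal it was 0.0720 (exact permutation p = 0.18), or 66.5% of the unmatched value. Neither the unmatched nor the matched difference exceeded the spread between arrays, so that chance is not excluded. A trend with signal and the class of transcript therefore cannot be told apart here.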

How the results depend on the processing

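Keeping flagged spots, the percentile without flagged spots, no minimum of values, leaving out slide 1, and quantile normalization with slide as a block were chosen after the data were examined; the first 2 of these had been seen before the main version was adopted. Quantile normalization, array medians, array weights and both blocks had also been fitted once to the values with flagged spots kept. Counts below are given as changed probes, mRNA probes, lncRNA probes, probes with a 2-fold change and named genes, which in the main values were 21, 13, 8, 5 and 5. With flagged spots kept they were 30, 18, 12, 7 and 6, with the percentile taken without flagged spots 19 (9 higher, 10 lower), 15, 4, 7 and 4, and with no minimum of values 21, 13, 8, 5 and 5.

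Normexp with quantile normalization gave 121 (64 higher, 57 lower), 70, 51, 2 and 44. Quantile normalization gave 3 named genes, and with slide as a block 3, 2, 1, 1 and 9. Centring on the array median gave 8 with a 2-fold change and 3 named genes. Without a filter on dim probes there were 4698 (4102 higher, 596 lower), 1546, 3152, 147 and 498. Array weights gave 55 (14 higher, 41 lower), 32, 23, 14 and 23, and eBayes with trend and robust settings 37 (12 higher, 25 lower) and 26 mRNA probes. Slide as a block gave 3 lncRNA probes. Leaving out slide 1, which leaves fewer arrays, gave 1, 0, 1, 1 and 0. The ordinary two-sample test gave 73 probes (30 higher, 43 lower) at an unadjusted p under 0.05 with a 2-fold change, and 0 after Benjamini-Hochberg. The mean of all probes gave 1 named gene. With each array left out the ranges were 0 to 48, 0 to 21, 0 to 27, 0 to 19 and 0 to 5. The causes of these differences between settings were not tested.

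With the replicate block all 5 counts were 0 in limma, with 14.1% of probes at an unadjusted p under 0.05. Same-numbered arrays correlated over 0.1 in 2 of 6 pairs, and 1 control correlated best with its own number. The mean correlation was 0.07 for same numbers and 0.13 for other numbers on the same slide. These values give no sign that the numbers pair the mice, but 6 pairs cannot exclude it.

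The shift of the known lncRNA list against all genes was -0.0285 and reversed to 0.0415 with quantile normalization, 0.0256 with normexp and 0.0413 with quantile normalization and slide as a block; with arrays left out it ranged from -0.0475 to 0.00988, the latter without control replicate 2. The list's own mean, which fry sets against 0 and not against all genes, was 0.0207, a different measure that shows no reversal of the shift. The list passed no threshold in camera or fry's directional test (p from 0.39 to 0.97). The fold changes of the 24 named genes kept their sign in all settings but not their size, 17 being over 1.5 times smaller with normexp, 3 without slide 1 and 1 with quantile normalization, alone or with slide as a block. Over the 24 named genes there were 532 comparisons on the same side of the threshold, 65 that lost it and 46 that gained it. Only the 5 genes past it in the main values could lose it, and the 532 include genes that stayed short of it. Of these 5, 4732491K20Rik kept it in 16 settings and lost it in 10, and Gm39515 in 16 and 11. The counts were 14 and 13 for 2310015A10Rik, 12 and 15 for A730020M07Rik and 11 and 16 for Gm34352. Signal over background limits the dim genes.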

Other observations

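These tests were chosen after the data were examined, except the count of splits. Because the protein-coding genes could not be named, the fixed lists were read through lncRNA genes that neighbour or overlap a list's genes or share a clone name with them. The hypothesis was that lncRNAs beside genes of one list may shift together. Of 52 such lists none passed, the smallest adjusted p in camera being 0.69, which does not exclude it. The 6 lists at that value follow by camera p. The 11 lncRNAs beside autophagy and lysosome genes had a median log2 fold change of -0.09 (3 higher, 8 lower), the 7 beside unfolded protein response genes -0.09 (2 higher, 5 lower), the 9 beside ependymal cell genes -0.11 (4 higher, 5 lower) and the 5 beside complement and phagocytosis genes -0.07 (1 higher, 4 lower). The 9 beside red blood cell genes had a median of 0.18 (8 higher, 1 lower) and the 19 beside choroid plexus genes of 0.16 (14 higher, 5 lower). For the known lncRNA list, 62 of the 100 splits gave a shift as large in size as the real 0.03, and the highest other was 0.13, so chance is not excluded.

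On the second principal component, which held 18.7% of the variance, all 6 control arrays lay above 0 and all 6 POCD arrays below (exact permutation p = 0.0022). Control replicates 1 and 2, on slide 1, had the highest values, 58.1 and 75.4, and the other control arrays ran from 3.05 to 9.69. The first component, with 21.8%, did not separate the groups (exact permutation p = 0.70).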
